A study of Homo sapiens with 4 samples.

How the data were processed

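ATAC-seq, which marks accessible DNA by the insertions of a transposase, was run on 4 libraries of human T cells, 1 per group, from 50000 cells per reaction and with 51-base reads from both ends, per the labels' protocols. The groups were taken from the sample titles: naive T cells at day 0, day-7 cells under Treg conditions, day-7 cells under Th17 conditions, and day-7 stimulated cells given UNC0642. The labels do not say whether the 4 libraries came from the same donors.

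The deposited data were 1 peak list per library, so peaks were called per sample and not on pooled samples. The aligner BWA, the peak caller MACS2 and the build hg19 (GRCh37) are named in the submitters' processing notes. Their versions, the calling threshold, the control, any shift of reads for the transposase and any filter of repeat-rich regions are not given in the sources used here. Each of these could move peak edges or the number of weak peaks. The fifth column of the deposited lists holds a score that the authors' peak caller gave each peak. Its scale is not given in the sources used here, it was not scaled between libraries, and it was used only to rank or filter peaks within their own list. The smallest gap between neighbouring peaks was 52 bases in each of the 4 lists. The lists give no read counts, so the depth of each library is unknown. Run codes in the file headers were shared by the 3 day-7 libraries and differed for the naive library.

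Analyses used the 22 autosomes and chromosome X. Chromosome Y, the mitochondrial genome and unplaced sequences were left out of every step because the cells came from people. Coordinates are given from 1 on hg19. A peak counted as shared when a peak of the other list overlapped it by at least 1 base. For each ordered pair of libraries the share of overlapped peaks was given with a 95% Wilson interval, the base-level Jaccard index (shared bases over bases in either list) and the overlap after random placement of the second list on the same chromosomes (10 seeded placements). Overlapping or touching peaks of the 4 lists were merged into regions, and each region was assigned to the set of libraries with a peak in it. Among Treg peaks without a Th17 peak, and among Th17 peaks without a Treg peak, the share with a peak in a further library was taken. The difference of both shares was given with a 95% Newcombe interval. Intervals cover counting error only. With 1 library per group no difference has a replicate check, no test across replicates could be run, and no p-value is given.

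The lists differed in length, so each comparison was repeated at equal length, with the 39942 highest-scoring peaks of each list. Lists of 1 length leave nearly equal numbers of unshared peaks on both sides of any pair, so this setting compares how much is shared, and not which list holds more sites. The naive list, the shortest, is kept whole in it. Other settings fixed before the data were examined were the upper 50% of each list by score, an overlap of at least 50% of both peaks, peaks within 500 bases counted as shared or merged, and autosomes alone. Chosen after seeing the data were the 10000 highest-scoring peaks and the upper 50% of a list against the whole other list, peaks set to 200 bases around their midpoint at equal length, and counts in windows of 100 kb. A weighting over score deciles was also chosen then. It used the 8 of 10 deciles with at least 20 sites in both sets, which left out the highest-scoring sites. Tied scores share a rank, so the upper 5 deciles hold slightly more peaks than the upper 50%. In a window, the net was the number of peaks of one library without an overlapping peak of the other, minus the reverse. Windows with a net of 3 or more either way were counted. The density of neighbours was the number of regions with a peak in 2 or more libraries within 500 kb. Its standard error came from a jackknife over chromosomes.

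Annotation by gene was not run. The table of gene positions at hand is for GRCh38.p14, coordinates were not converted, and no sequence or annotation of hg19 was used. The planned promoter shares, gene loci, gene lists, markers of other cell types, motifs and the comparison with promoters left out were therefore not analysed here. The rule for named genes has a form for this case, fixed before the data were examined: the highest-scoring peak of each single-library class and the 5 highest-scoring regions of each class are named by coordinates. Regions in several libraries were ordered by the highest percentile that they reached in the scores of any of these lists, a choice made after seeing the data. Windows are named from those with the largest net among windows with a net of 3 or more, in the same direction, both as deposited and at equal length. They were chosen after their values were seen.

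Overlaps were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The overlap counts were checked against bedtools 2.31.1 in 24 comparisons, with 0 differing. On simulated lists, 6 known shares of Treg-only and Th17-only sites were recovered within 0.659 percentage points over 26666 sites. The 9 region classes were recovered exactly over 20000 simulated sites. Both simulations check the code alone. The simulated shares were drawn from these same sites with slightly moved edges. The sites simulated for the classes were spaced too widely for neighbours to merge, so merging of close peaks was not tested.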

Results

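Accessible chromatin was mapped by ATAC-seq in naive T cells from the blood of healthy donors at day 0 and in 3 kinds of culture started from naive T cells and taken at day 7. The 3 cultures were stimulated with antibodies to CD3 and CD28 (2 µg/ml each). The Treg culture also received IL-2 (10 ng/ml) and TGFβ (5 ng/ml), a mix that drives regulatory T cells. The Th17 culture received IL-21 (100 ng/ml), IL-6 (50 ng/ml), IL-1β and IL-23 (20 ng/ml each) and TGFβ (5 ng/ml) with antibodies against interferon γ and IL-4. The inhibitor culture received UNC0642 (2 µM) and no polarizing cytokines. UNC0642 inhibits G9a (EHMT2) and its relative GLP (EHMT1), enzymes that methylate histone H3 and whose mark goes with silent chromatin. From day 5, the cultures were kept in fresh medium with the stimulating antibodies. Each group had 1 library, so no difference below could be set against a spread between replicates, and intervals are 95% intervals of counting error only.

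On the autosomes and chromosome X the naive library held 39942 peaks over 20.2 Mb, the Treg library 79179 peaks over 35.5 Mb, the Th17 library 65102 peaks over 33.0 Mb and the inhibitor library 65762 peaks over 30.1 Mb. The day-7 lists were thus 1.98, 1.63 and 1.65 times as long as the naive list. Median peak widths were 435 bases (naive), 370 bases (Treg), 413 bases (Th17) and 378 bases (inhibitor). The lists give no read depth, so the number of peaks cannot be set against it.

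The first question was which sites differ between naive cells and cells cultured for 7 days. Most naive sites were also open at day 7: 90.1% of naive peaks overlapped a Treg peak, 88.9% a Th17 peak and 89.2% an inhibitor peak, against 2.31% to 2.76% after random placement. In the other direction, 45.4% (45.1 to 45.7) of Treg peaks, 53.6% (53.2 to 54.0) of Th17 peaks and 54.1% (53.8 to 54.5) of inhibitor peaks overlapped a naive peak. The merged lists gave 88685 regions. Of these, 33097 (37.3%, 37.0 to 37.6) had a peak in all 4 libraries, 19564 (22.1%, 21.8 to 22.3) had one in all 3 day-7 libraries and none in naive cells, and 2560 (2.89%, 2.78 to 3.00) had one in naive cells alone. At equal length there were 5862 regions in the 3 day-7 libraries without naive and 7680 in naive cells alone. This cut keeps the naive list whole and shortens only the day-7 lists, so naive-only regions can only gain in number. The reversed order of these classes therefore says nothing about the cells. At equal length the overlap of naive with day-7 lists was 71.2% to 74.8%, while day-7 lists overlapped one another by 84.1% to 90.7%.

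**Figure D1:**
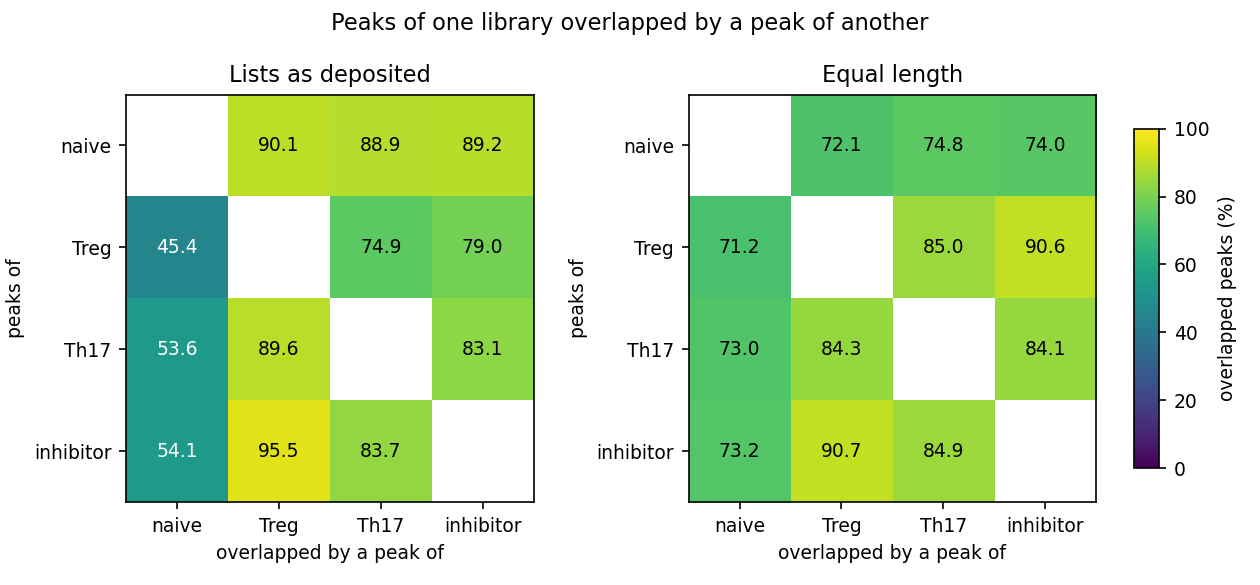
Percent of the peaks of one library (vertical axis) that a peak of another library (horizontal axis) overlapped by at least 1 base, for the lists as deposited and for the 39942 highest-scoring peaks of each list; colour runs from 0 to 100%. At equal length the 3 pairs with the naive library lie between 71.2% and 74.8% and the pairs of day-7 libraries between 84.1% and 90.7%.

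The highest-scoring sites present in all 3 day-7 libraries and absent from the naive list were at chromosome 12, 24992063 to 24992785, chromosome 4, 6182353 to 6183202, chromosome 20, 42379621 to 42380559, chromosome 9, 117453155 to 117453820, and chromosome 6, 111265777 to 111266397. The site on chromosome 12 stood at percentile 97.1 of the scores in the Treg list, 97.6 in the Th17 list and 94.4 in the inhibitor list. The highest-scoring naive-only site, at chromosome 11, 60679678 to 60680232, stood at percentile 89.0 of the naive scores. It was followed by chromosome 16, 29767892 to 29768416, chromosome 12, 132670291 to 132670733, chromosome 15, 93356679 to 93357139, and chromosome 10, 31610311 to 31610966. Among the 10000 highest-scoring peaks, 3.12% (2.80 to 3.48) of Treg, 2.35% (2.07 to 2.67) of Th17 and 2.13% (1.86 to 2.43) of inhibitor peaks had no naive peak. The reverse shares, of top naive peaks without a day-7 peak, were 0.33%, 0.33% and 0.25%.

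Clusters of sites were compared in 100-kb windows. The window at chromosome 3, 46300001 to 46400000, held 1 naive peak, 17 Treg peaks, 8 Th17 peaks and 15 inhibitor peaks. At chromosome 7, 92200001 to 92300000, there were 2 naive, 16 Treg, 11 Th17 and 15 inhibitor peaks. The window at chromosome 5, 142400001 to 142500000, held no naive peak and 13 Th17 peaks, with 9 in each of the other day-7 libraries. In the opposite direction, chromosome 15, 99100001 to 99200000, held 9 naive peaks and 2 Treg, 3 Th17 and 4 inhibitor peaks. The Treg list had a net excess of 3 or more peaks over naive in 6251 windows and the reverse in 29, and the counts at equal length were 507 and 754. Th17 against naive gave 3567 and 55 windows (446 and 699 at equal length), and inhibitor against naive gave 3688 and 30 (442 and 645). As lists of 1 length leave nearly as many unshared peaks on either side (11150 naive and 11515 Treg peaks), the equal-length counts do not say which direction prevailed. The limit was met in both settings in 507, 446 and 442 windows with more day-7 peaks and in 29, 55 and 30 with more naive peaks. These counts were fixed in advance. The cut removes day-7 peaks and no naive peak, so a day-7 excess can only shrink and a naive excess only grow. Each count repeats the smaller one of its direction and shows no agreement between settings.

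**Figure D2:**
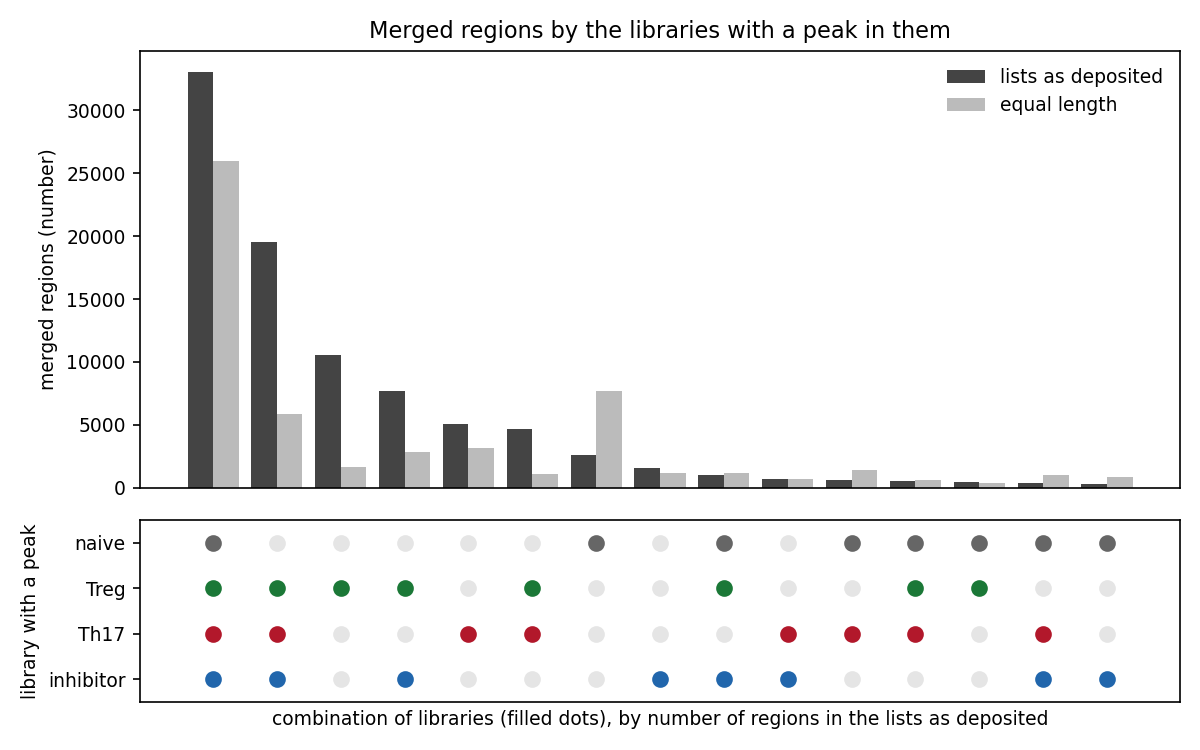
Number of merged regions for each combination of libraries with a peak (filled dots), as deposited (dark bars) and at equal length (light bars). Regions of all 4 libraries are the most numerous class in both settings (33097 and 25981), and naive-only regions number 2560 as deposited and 7680 at equal length. The equal-length setting shortens only the day-7 lists.

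The comparison of Treg with Th17 cells asks where both ways of polarizing the cells differ. They shared most sites: 89.6% (89.4 to 89.8) of Th17 peaks overlapped a Treg peak and 74.9% (74.6 to 75.2) of Treg peaks a Th17 peak, with a Jaccard index of 0.674. There were 19902 Treg peaks without a Th17 peak and 6764 Th17 peaks without a Treg peak. At equal length these numbers were 6002 and 6281, which lists of 1 length bring close together whatever the cells, so the excess of Treg sites cannot be judged there. Of the 10000 highest-scoring peaks, 6 Treg peaks lacked a Th17 peak and 4 Th17 peaks lacked a Treg peak. Set against the whole other list, 1873 of the upper 50% of Treg peaks by score (4.73% of 39589, 4.53 to 4.95) overlapped no Th17 peak, and 415 of the upper 50% of Th17 peaks (1.27% of 32551, 1.16 to 1.40) overlapped no Treg peak. The whole Treg list is longer (79179 against 65102 peaks), which by itself lowers the number of Th17 peaks without an overlap.

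Sites in the Treg library alone numbered 10588, and the strongest, at chromosome 2, 114606522 to 114607181, stood at percentile 70.5 of the Treg scores. The next were at chromosome 1, 38002967 to 38003430, chromosome 12, 6683738 to 6684396, chromosome 9, 33552369 to 33552709, and chromosome 3, 10408434 to 10408846. Sites in the Th17 library alone numbered 5076, and the strongest, at chromosome 13, 110707355 to 110707909, stood at percentile 85.1 of the Th17 scores. The median percentile in the own list was 15.0 for Treg-only and 14.5 for Th17-only regions. The strongest Th17-only site was followed by chromosome 6, 39222723 to 39223330, chromosome 5, 142554439 to 142555023, chromosome 7, 105550547 to 105551029, and chromosome 5, 173972835 to 173973429. At equal length there were 1619 Treg-only and 3184 Th17-only regions. That cut drops the weakest peaks and takes more of them from the Treg list than from the Th17 list. The reversed order therefore does not say which cells have more sites of their own. The window at chromosome 9, 20500001 to 20600000, held 16 Treg peaks, 13 inhibitor peaks, 5 Th17 peaks and 2 naive peaks. At chromosome 6, 106600001 to 106700000, the counts were 15 Treg, 12 inhibitor, 6 Th17 and 2 naive peaks. More Th17 peaks were found at chromosome 15, 61000001 to 61100000, with 13 Th17, 9 Treg, 6 inhibitor and 4 naive peaks, and at chromosome 3, 127500001 to 127600000, with 9 Th17 peaks, 4 Treg peaks, 4 inhibitor peaks and no naive peak. Treg exceeded Th17 by 3 or more in 1832 windows and Th17 exceeded Treg in 125. At equal length these were 170 and 141, and 104 and 12 windows met the limit in both settings. These last counts carry over the longer Treg list from the lists as deposited. They do not say which cells have more clusters of their own.

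**Figure D3:**
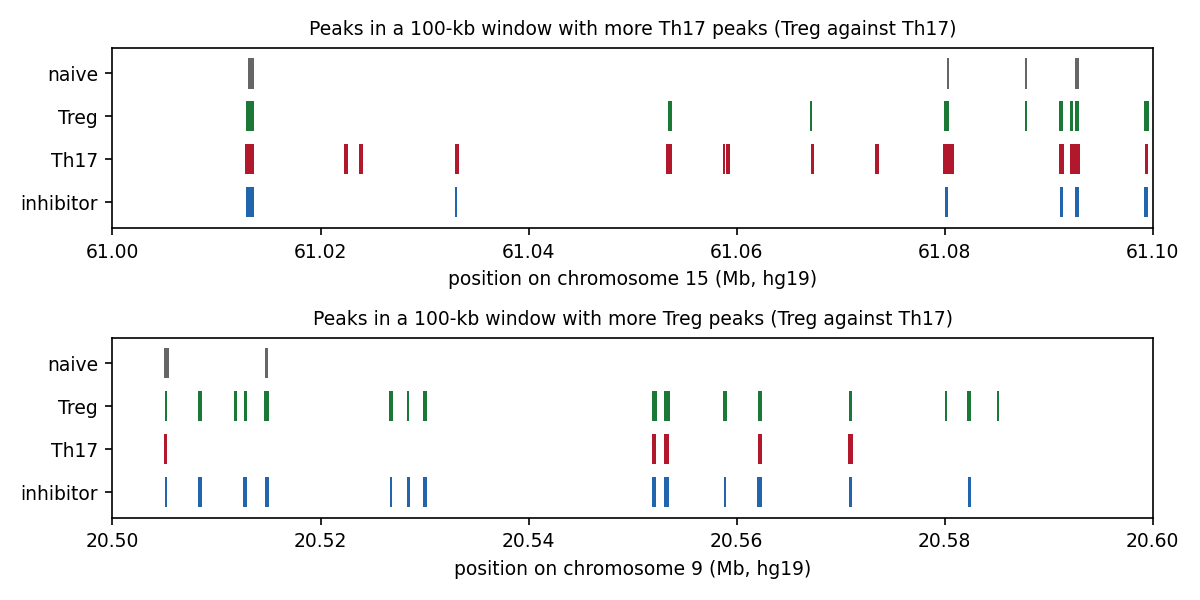
Peaks of the 4 libraries (rows of boxes, drawn to scale) along a pair of 100-kb windows on hg19, one on chromosome 15 with 13 Th17 and 9 Treg peaks and one on chromosome 9 with 16 Treg and 5 Th17 peaks. On chromosome 9 the inhibitor library has 13 peaks, and on chromosome 15 it has 6.

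The comparison of the inhibitor culture with the polarized cultures asks whether stimulated cells given the G9a inhibitor resemble either state in their open sites. By Jaccard index and at equal length, the inhibitor library was closest to the Treg library. Of its peaks, 95.5% (95.3 to 95.6) overlapped a Treg peak and 83.7% (83.4 to 84.0) a Th17 peak. In the reverse direction the order turned around: 79.05% of Treg peaks and 83.13% of Th17 peaks overlapped an inhibitor peak. The longer Treg list can favour Treg in the first direction and Th17 in the second. The Jaccard index was 0.738 for inhibitor with Treg, 0.680 for inhibitor with Th17 and 0.524 for inhibitor with naive. At equal length 90.7% of inhibitor peaks overlapped a Treg peak and 84.9% a Th17 peak, with Jaccard indices of 0.783 and 0.690. There 90.63% of Treg peaks and 84.05% of Th17 peaks overlapped an inhibitor peak. Among the 10000 highest-scoring inhibitor peaks, 0 lacked a Treg peak and 3 lacked a Th17 peak, too few to order both libraries. Of the upper 50% of inhibitor peaks by score, 12 of 32881 overlapped no peak of the whole Treg list and 902 no peak of the whole Th17 list. The whole Treg list is longer (79179 against 65102 peaks), which by itself leaves fewer peaks without an overlap.

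Sites in the inhibitor library alone were few and weak. They numbered 1536 (1.73% of regions, 1.65 to 1.82), and the strongest, at chromosome 3, 108447834 to 108448175, stood at percentile 53.3 of the inhibitor scores. The next were at chromosome 9, 32529621 to 32529901, chromosome 2, 46666725 to 46667003, chromosome 11, 1726971 to 1727329, and chromosome 12, 52998698 to 52998993. Against Treg, the inhibitor library had a net excess of 3 or more peaks in 19 windows and a net deficit in 1302, and at equal length in 67 and 35. Only 3 windows had more inhibitor peaks in both settings, out of the 19 as deposited, where the longer Treg list weighs against such windows. Chromosome 4, 49100001 to 49200000, held 8 inhibitor, 4 Treg, 9 Th17 and 9 naive peaks. At chromosome 9, 92100001 to 92200000, there were 16 inhibitor, 13 Treg, 12 Th17 and 12 naive peaks. Chromosome 2, 92300001 to 92400000, held 7 inhibitor, 4 Treg, 6 Th17 and 6 naive peaks. On chromosomes 4 and 2 the Treg library thus held the fewest peaks, with naive and Th17 near the inhibitor count. The windows on chromosomes 4 and 2 lie beside centromeres, where repeats make short reads hard to place. More Treg peaks in both settings were found in 10 windows, among them chromosome 4, 6000001 to 6100000, with 6 Treg, 6 Th17 and 1 inhibitor peaks. The counts of 3 and 10 windows do not say which library has more clusters of its own, as list length enters both.

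Sites that separate Treg from Th17 were then looked up in the inhibitor library. Of the 19902 Treg sites without a Th17 peak, 44.2% (43.5 to 44.9) had an inhibitor peak, and of the 6764 Th17 sites without a Treg peak 15.4% (14.6 to 16.3) did, a difference of 28.8 percentage points (27.7 to 29.9). At equal length the shares were 66.9% and 26.2%. The difference widened with the score of the site. In the upper 5 score deciles of their own list, 1828 of 1907 Treg sites (95.9%, 94.9 to 96.7) and 123 of 422 Th17 sites (29.1%, 25.0 to 33.7) had an inhibitor peak, and in the lowest decile 19.5% and 10.5% did. Naive cells, measured in the same way as the starting state, went the opposite way: 7.89% (7.53 to 8.28) of the Treg sites and 15.0% (14.1 to 15.8) of the Th17 sites had a naive peak, and 25.0% and 38.9% at equal length.

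**Figure D4:**
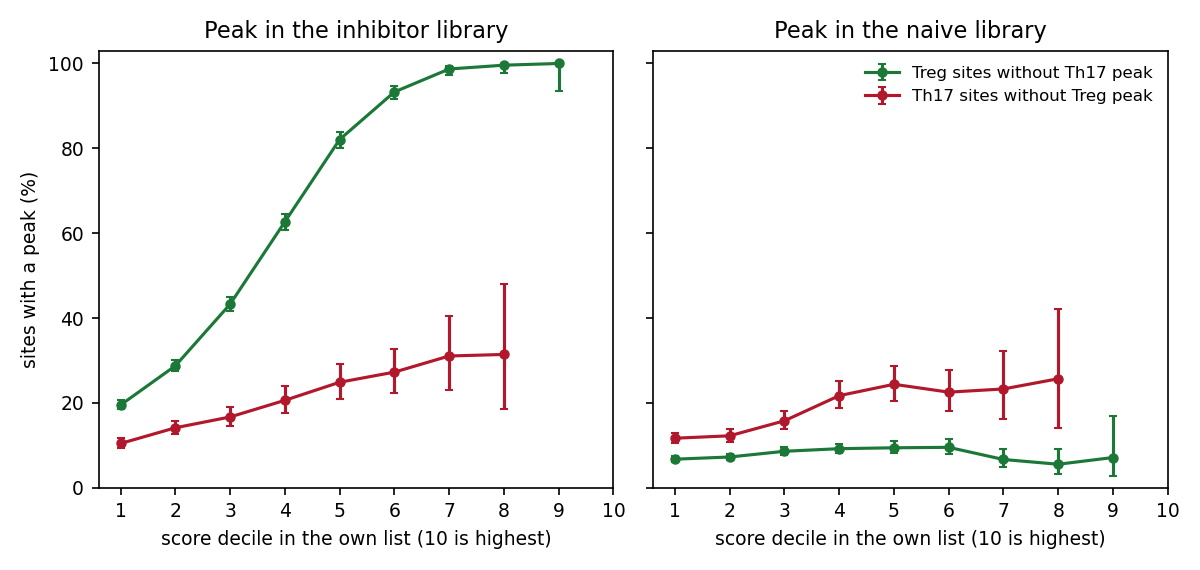
Percent of Treg sites without a Th17 peak (green) and of Th17 sites without a Treg peak (red) that had a peak in the inhibitor library (left) or the naive library (right), by decile of the score in their own list; bars are 95% Wilson intervals and deciles with fewer than 20 sites are left out. In the inhibitor library the Treg sites run from 19.5% in the lowest decile to 99.6% in decile 8 and 100.0% in decile 9, and the Th17 sites from 10.5% to 31.4% in decile 8.

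Regions shared by Treg and inhibitor, with no peak in Th17 or naive cells, numbered 7647 (8.62% of regions, 8.44 to 8.81), against 656 (0.74%, 0.685 to 0.798) for Th17 and inhibitor and 4635 (5.23%, 5.08 to 5.37) for Treg and Th17. The equal-length counts were 2872, 649 and 1076. The highest-scoring region of Treg and inhibitor was at chromosome 3, 50610734 to 50611844, at percentile 93.8 of the Treg scores and 90.8 of the inhibitor scores. The next were at chromosome 17, 76409049 to 76409715, chromosome 2, 158333607 to 158334294, chromosome 10, 63544313 to 63545059, and chromosome 1, 85435361 to 85436003. The 5 highest-scoring regions of Th17 and inhibitor were at chromosome 2, 62532723 to 62533430, chromosome 19, 38772412 to 38773045, chromosome 13, 67622400 to 67623063, chromosome 11, 36015919 to 36016362, and chromosome 4, 55612288 to 55612911. The first of them stood at percentile 84.8 in the Th17 list and 16.2 in the inhibitor list. Those of Treg and Th17 without inhibitor were at chromosome 14, 30824424 to 30825175, chromosome 11, 93263225 to 93263835, chromosome 2, 64566003 to 64566690, chromosome 5, 157809405 to 157809900, and chromosome 7, 104008400 to 104008938. The first of these stood at percentile 83.3 in the Th17 list and 6.71 in the Treg list.

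The highest-scoring regions of all 4 libraries were at chromosome 1, 569227 to 569702, 567959 to 568441, 565070 to 565503 and 121484123 to 121485488, and at chromosome 21, 9825637 to 9826425. The stretch near the start of chromosome 1 holds a nuclear copy of mitochondrial DNA, and the remaining sites lie in or beside repeats, so reads from elsewhere can pile up there. These samples include no stimulated library without both inhibitor and polarizing cytokines, so the values do not separate the action of UNC0642 from that of stimulation and culture. The naive library also came from another sequencing run than the 3 day-7 libraries, so the run and the day of culture cannot be told apart.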

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

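The tests on the 10000 highest-scoring peaks, on 200-base peaks, over score deciles and in windows were chosen only after the result was seen. With depth unknown, the number of weak peaks per library is limited in a way these lists do not show. Treg, Th17 and inhibitor peaks overlapped naive peaks by 71.2%, 73.0% and 73.2% at equal length, 45.8%, 54.3% and 55.1% in the upper 50% by score, 41.1%, 48.7% and 50.05% with an overlap of 50% of both peaks, 47.7%, 55.4% and 56.2% within 500 bases, and 96.9%, 97.7% and 97.9% for the 10000 highest-scoring peaks against the whole list. In the same order of settings, inhibitor peaks overlapped Treg peaks by 90.7%, 96.6%, 92.1%, 96.0% and 100.0%, and Th17 peaks by 84.9%, 84.8%, 78.4%, 84.8% and 99.97%, so that Treg lay above Th17 in the first 4. With 10000 peaks the shares were saturated, with 0 and 3 peaks lacking an overlap, and give no order. Of the first 4 settings, the reverse direction put Treg above Th17 only at equal length (90.63% and 84.05% overlapped by inhibitor). These shares were 80.25% and 85.03% in the upper 50%. They were 76.5% and 79.17% with an overlap of 50% of both peaks, and 80.83% and 84.48% within 500 bases. The Treg list is the longer one in these last settings. Regions of all 4 libraries numbered 17085 in the upper 50% by score, and inhibitor-only regions 564. Naive-only regions numbered 7680 at equal length and 1316 in the upper 50%, and regions of the 3 day-7 libraries without naive 5862 and 10138. Fewer peaks entered both settings, and at equal length only the day-7 lists were cut. The share of Treg sites without a Th17 peak that had an inhibitor peak was 66.9% at equal length, 45.5% within 500 bases, 67.2% with peaks of 200 bases at equal length and 42.6% weighted over score deciles. The share of Th17 sites without a Treg peak was 26.2% at equal length, 14.3% in the upper 50%, 20.4% with an overlap of 50% of both peaks, 27.0% with 200-base peaks and 16.4% weighted. Their difference stayed above 0 in all 6 alternatives, at 40.7 points at equal length, 30.4 in the upper 50%, 24.4 with an overlap of 50% of both peaks, 40.2 with 200-base peaks and 26.2 weighted, the rest within the interval. In the naive library it was below 0 throughout, at -13.9 points at equal length and -5.72 with an overlap of 50% of both peaks. Treg sites without Th17 minus Th17 sites without Treg came to 13138 as deposited, 6749 in the upper 50%, -279 at equal length and -1 with 200-base peaks at equal length. The last pair changed sign because equal lists leave nearly equal remainders. The cause of the other shifts was not tested. Of the remaining values, 20 of the main answers stayed within their interval or within 1.5 times the main count. Among single overlaps, smaller classes and windows, 20 did so, 32 lay above and 27 below. Promoter shares, gene loci, gene lists, motifs and promoters left out were not run under any setting, for lack of an hg19 annotation and sequence here.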

Other observations

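The tests of weak sites near the calling threshold, peak width, score make-up, sequencing run and absent Th17 cytokines were chosen only after the result they bear on was seen, as were the counts of kept naive sites, chromosomes and neighbouring sites. For weak sites, peak width and site-poor stretches, the outcome that would count against each was written before its own value was seen. The test of list length used the equal-length setting fixed before the data were examined, and was read as a test of that explanation only afterwards.

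Of 1418 regions with a naive peak and a peak in exactly 1 day-7 library, 623 (43.9%, 41.4 to 46.5) were kept in Th17, 472 (33.3%, 30.9 to 35.8) in Treg and 323 (22.8%, 20.7 to 25.0) in the inhibitor library. At equal length there were 2624 such regions, 1440 in Th17 (54.9%), 816 in the inhibitor library (31.1%) and 368 in Treg (14.0%), so the order of Treg and inhibitor turned around. Asking for exactly 1 library counts against Treg and inhibitor, whose lists overlapped most: as deposited, 1028 further naive regions were shared by these alone, against 357 by Th17 and inhibitor and 523 by Treg and Th17. At equal length these counts were 1127, 982 and 645, so this bears less on the equal-length shares. Over all naive peaks, 90.1% overlapped a Treg peak and 88.9% a Th17 peak as deposited, and the order turned around at equal length, with 72.1% (71.6 to 72.5) and 74.8% (74.4 to 75.3). The equal-length cut keeps every naive peak and takes more peaks from the Treg list than from the other day-7 lists. Neither turn in order thus says which culture kept more naive sites. Sites that separate the inhibitor library from Treg also differed in how often they held a naive peak. Of the 2972 inhibitor peaks without a Treg peak, 24.5% overlapped a naive peak, against 6.74% of the 16589 Treg peaks without an inhibitor peak, and at equal length 49.6% and 27.5% did. Sites that separate the inhibitor library from Th17 differed little: 13.1% of inhibitor peaks without a Th17 peak and 10.8% of the reverse overlapped a naive peak. At equal length these shares were 32.4% and 33.0%. Neither contrast was weighted by score.

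Sites open in all 4 libraries were spread over chromosomes differently from those of fewer libraries. Chromosome 19, which is rich in genes, held 5.97% (5.72 to 6.23) of the regions of all 4 libraries, but 3.08% (2.85 to 3.33) of those in the 3 day-7 libraries without naive, 2.81% (2.24 to 3.53) of naive-only regions and 2.21% (1.90 to 2.56) of those in Treg and inhibitor alone. Chromosome 17 held 6.13%, 4.07%, 5.04% and 3.94% of the same classes. The median number of shared sites within 500 kb was 45 around regions of all 4 libraries, 44 around naive-only, 39 around Treg-only, 37 around inhibitor-only and 34 around Th17-only regions. Places with at most 28 such sites within 500 kb held 40.0% (38.6 to 41.3) of Th17-only regions and 19.4% (17.9 to 21.0) of naive-only regions.

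The naive list shared fewer sites with the day-7 lists than they shared with each other. At equal length the lowest overlap among day-7 pairs still exceeded the highest with naive by 9.21 points, but this does not decide on unequal list length as a cause. The cut keeps the naive list down to its weakest peaks, and the day-7 lists only at their higher scores. A lower overlap with naive could follow from that alone. Weak day-7 sites near the calling threshold are argued against as the whole cause, since 2.13% or more of the 10000 highest-scoring peaks of each day-7 list had no naive peak, while at most 0.06% lacked a peak of another day-7 list. In the reverse direction, 0.25% to 0.33% of the 10000 highest-scoring naive peaks had no peak of a day-7 list. The naive list is the shortest, so its length may add to the first share. The sequencing run cannot be told apart from the day of culture, because 0 of the day-7 libraries shared the run of the naive library, and a lower depth of the naive library stays open as the lists give none. Stimulation and 7 days of culture, which the design names, may account for the pattern and were not tested separately.

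Treg sites without a Th17 peak held inhibitor peaks more often than Th17 sites without a Treg peak did. The Treg sites were less concentrated in the lowest score decile of their own list (26.7% against 35.8% of the Th17 sites), but this score make-up is argued against as the whole cause, since weighting to the same score deciles left a difference of 26.2 points (25.1 to 27.3). Peak width is argued against, since 200-base peaks at equal length gave 40.2 points (38.7 to 41.7). An action of the inhibitor cannot be told apart from the mere absence of the Th17 cytokines, because 0 stimulated libraries had neither inhibitor nor polarizing cytokines. Cells that received no Th17 cytokines may lack Th17 sites whatever UNC0642 does, and such a control would be needed to tell these hypotheses apart.

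As G9a is known for its part in silent chromatin, a hypothesis was that its loss opens sites in site-poor stretches, which would place inhibitor-only sites among fewer neighbours than other single-library sites of like score. Inhibitor-only sites had a median of 37 shared sites within 500 kb, against 39 for Treg-only and 34 for Th17-only sites up to the same score percentile. Regions of the 3 day-7 libraries without naive, not limited by score, also had a median of 37. The differences were -2 (jackknife SE 2.1) from Treg-only and 3 (SE 1.96) from Th17-only sites. Both lie within 2 SE of 0, and the outcome set beforehand as counting against the hypothesis, a median not lower by more than 2 SE, can be met by imprecision alone. The jackknife is also a rough guide for medians of whole numbers, as its SE of 0 for all naive-only regions shows. The hypothesis stays open, the more so as G9a activity was not measured and no stimulated library without both inhibitor and polarizing cytokines is among these samples.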
